A study of Mus musculus with 6 samples.

How the data were processed

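Circular RNAs (circRNAs), which are closed by back-splicing and have no free ends, were measured on a mouse circRNA microarray in small intestine of 8-week-old C57BL/6 mice. Of the 6 arrays, 3 came from sham animals (replicates 1, 2 and 3) and 3 from intestinal ischaemia/reperfusion, I/R (replicates 6, 7 and 9, whose labels carry 4 h). The group and the number of each sample were taken from its label. The labels do not state that every sample is a separate animal, so p-values measure the spread between these samples.

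Per the labels' protocols, tissue was immersed in 4% paraformaldehyde, RNA was extracted with TRIzol, and total RNA was digested with RNase R, an exonuclease that degrades linear RNA, before random-primed labelling with Cy3. Per the file headers, the authors' scanner files hold spot intensity from Agilent Feature Extraction 11.0.1.1 for an array designed on mm9, and the processed intensity is background-subtracted but not normalized between arrays. The submitters' processing notes name Agilent Feature Extraction and limma without versions. The authors' deposited value table holds log2 values for 9821 probes. Its columns have medians of 6.56, 6.56, 6.56, 6.56, 6.56 and 6.55 (sham 1, 2 and 3, I/R 6, 7 and 9) and share a maximum of 16.9, as quantile normalization leaves them, and they rank probes as the scanner's median signal does (Spearman's rho across probes of 0.995 to 0.997 per array). The background correction and the filter behind that table are not stated. Differences in it were close to those with normexp background correction and quantile normalization, as given below.

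Each array held 15712 spots, of which 536 were control spots and were left out. The remaining 14330 probes comprised 14236 circRNA probes with 1 spot each, 50 probes for linear transcripts, 14 probes named as circRNA controls, 15 custom probes and 15 negative probes. Linear transcript probes had 10 spots each, which were averaged. Spots marked as outliers by the scanner software were left out, 18 of them in circRNA probes, and no spot was saturated. On average 62.2% of the non-control probes were well above background, so the main values were log2 processed intensity minus each array's 75th percentile over all non-control spots. Values below are on this log2 scale unless stated. A probe was tested when it was well above background on at least 3 of the 6 arrays, which held for 9492 circRNA probes (66.7%).

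I/R was compared with sham in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Single values per array were compared by an exact two-sided permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. The arrays were parted into 2 sets by the scan date in the file headers, and the sets are called slides here. Slide 1 held sham 1 and I/R 6, which share a scan date. Slide 2 held the other 4 arrays, which do not have that date, so slide could be fitted as a block. The number of arrays limits the precision. Arrays with 9477 probes, of which 200 were changed, were simulated. Limma recovered 2.98% of the probes changed by 1 on the log2 scale, 54.6% of those changed by 2 and 85.4% of those changed by 3. Of its calls 5.33% were false. The simulated probes were drawn independently, with no slide difference and no background floor, so these rates may not hold for the real arrays.

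The files do not pair circRNA probes with host genes, so host gene lists, the agreement of circRNAs from one host gene, and the naming of host genes were not run. By the rule fixed before the data were examined, the named circRNA probes are those with the largest fold past the threshold, filled by the smallest unadjusted p among probes with an unadjusted p under 0.05 and a fold of at least 1.5, and for unnamed probes 2 IDs per direction are printed. Where a probe was not well above background on any array of a group, its fold is given as a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own. Linear transcript probes were named through RefSeq transcripts of the GRCm38.p6 assembly, and 44 of 50 matched. Their test, the share of signal in the brightest probes and the comparison of slides were chosen after seeing the data. The linear transcripts were first fitted over all 50 probes, and that fit is the one reported. A fit limited to the 36 probes above background on at least 3 arrays was made later and gives a different count, which is stated beside the result. The named linear transcripts are those above background on at least 3 arrays with an unadjusted p under 0.05, the members of the gene lists fixed beforehand, and others chosen after their values were seen.

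Alternatives for normalization, background, filter, value table, variance model, array weights, threshold, slide and each replicate left out were fixed before the data were examined. Normexp background correction (offset 50) was planned on the mean signal. It was run on the scanner's median signal and median local background in its place. The offset of 50 is added to every signal and is of similar size to the arrays' 75th percentiles of processed intensity (57.6 to 108). By itself it shrinks the log2 differences of dim probes. Where percentile scaling follows, the offset also draws the arrays' percentiles together, so less of the brightness difference between arrays is removed from bright probes.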

Results

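Intestinal ischaemia/reperfusion interrupts and then restores blood flow to the gut. The arrays compared circRNA levels in small intestine after I/R with those after a sham operation, with 3 arrays per group. The 75th percentile of processed intensity was 57.6, 82.9 and 70.3 on sham 1, 2 and 3, and 79.5, 108 and 85.4 on I/R 6, 7 and 9. The group means differed 1.30-fold (exact permutation test over all arrays, two-sided, p = 0.2). Within each slide every I/R array was brighter than every sham array, 1.38-fold on slide 1 and 1.03-fold to 1.54-fold on slide 2.

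More circRNA probes were well above background after I/R on every array. The counts out of 14236 probes were 9006, 5845 and 8015 for sham 1, 2 and 3, and 9836, 11113 and 9280 for I/R 6, 7 and 9. The means were 7622 ± 1617 for sham and 10076 ± 940 for I/R (SD, n = 3 each). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. Sham 2 stood apart, with 4880 circRNA probes at its lowest signal against 2024 on sham 3 and 1 on each other array, and without it the difference of 2454 probes was 1566. The order held on slide 1, with 9006 in sham 1 and 9836 in I/R 6, and on slide 2. One threshold on the unscaled signal for all arrays was also applied, a test chosen after seeing the data. The counts were then 5144, 5843 and 5781 for sham and 6123, 7151 and 6287 for I/R (exact two-sided permutation p = 0.1). An unscaled threshold counts more probes on a brighter array. With one threshold on the scaled level, which itself draws counts together, the groups overlapped (exact two-sided permutation p = 0.6). The counts there were 6177, 5843 and 6300 for sham and 6247, 6268 and 6202 for I/R. Of all circRNA probes, 5685 were well above background on all 6 arrays and 2605 on none.

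**Figure D1:**
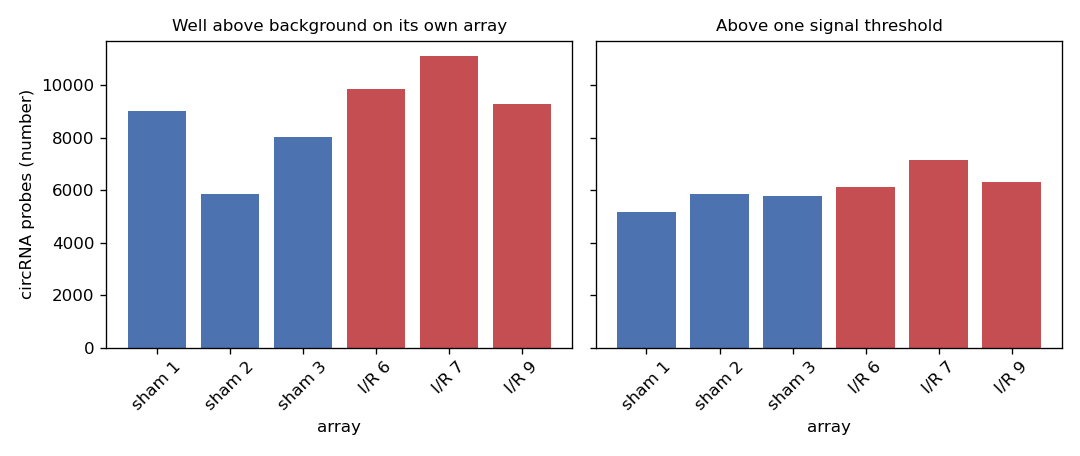
Number of circRNA probes on each array (sham blue, I/R red), counted as well above background on the array itself (left) or above one threshold on the unscaled signal shared by all arrays (right). On the left the I/R arrays lie between 9280 and 11113 and the sham arrays between 5845 and 9006; on the right they lie between 6123 and 7151 and between 5144 and 5843.

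No circRNA probe passed the threshold between I/R and sham. Limma called 0 of 9492 tested probes, with a smallest adjusted p of 0.146, and 801 probes (8.44%) had an unadjusted p under 0.05, where 475 would be reached by chance at 5%. Of these 801, 518 were higher in I/R and 283 lower, but the balance turned with the scaling, to 358 and 517 with quantile normalization and to 224 and 516 with the percentile taken over probes detected on all arrays. The excess over 5% lay in dim probes. Under a mean log2 signal of 4 (2038 probes) 223 were higher and 42 lower, and at 4 to 6 (3606 probes) 193 and 143. At 6 to 8 (2040 probes) they were 43 and 64, and at 8 to 10 (983 probes) 40 and 17. Over 10 (825 probes) they were 19 and 17. Above 6 the shares were thus near 5%. All 3 I/R arrays lay above all 3 sham arrays for 836 probes (8.81%) and below them for 588 (6.19%), where chance alone separates 5% of probes each way. With slide as a block limma again called 0 probes, with 1179 at an unadjusted p under 0.05, and within slide 2 it called 0, with 658. Without I/R 6 the unadjusted count was 398 and without I/R 7 it was 359. Array weights called 4 probes.

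ASCRP4011796 and ASCRP4007644 had the smallest p-values among circRNA probes higher in I/R, and ASCRP4000474 and ASCRP4000927 among those lower. All 4 shared an adjusted p of 0.146 in limma and are given as values, not as changes. ASCRP4011796 was not well above background on any sham array and was on all 3 I/R arrays, at -4.46 ± 0.48 and -1.24 ± 0.48 (SD, n = 3), which makes it at least 2.09-fold higher in I/R. ASCRP4007644 had the same pattern, at -3.96 ± 0.03 and -2.07 ± 0.19, and was at least 1.17-fold higher in I/R. On sham 2 both probes lay at -3.92, and on sham 3 ASCRP4011796 lay at -4.67. Other dim probes repeat these values on those arrays. The sham SDs and the p-values of these probes therefore rest in part on floor values, not on measured spread. ASCRP4000474 was well above background on all 6 arrays, at -0.06 ± 0.10 in sham and -2.09 ± 0.10 in I/R, a difference of -2.04 (SE 0.23, 95% interval -2.57 to -1.51). ASCRP4000927 was well above background on the sham arrays only, at -1.26 ± 0.30 against -3.46 ± 0.18, and was at least 4.12-fold higher in sham. The difference of ASCRP4000474 was -2.13 on slide 1 and -1.99 on slide 2. These sizes depend on the background correction and its offset. With normexp ASCRP4000474 differed by -0.85. The measured differences of ASCRP4011796, ASCRP4007644 and ASCRP4000927 were then 0.40, 0.08 and -0.71, which as folds lie below the bounds given for them. The normexp offset of 50 by itself draws low signals together, so this shrinkage does not tell background from offset. With array weights these 4 probes were the ones past the threshold, at an adjusted p of 0.0426 each in limma, within a range of 0.0426 to 0.974 over all alternatives.

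The probes well above background in 1 group alone were almost all I/R probes. On all 3 I/R arrays and no sham array 316 circRNA probes were detected, and in the opposite direction only ASCRP4000927 was. The arrays differ in their detection limits. The lowest signal among probes well above background was 7.61, 26.95 and 13.6 on sham 1, 2 and 3. On I/R 6, 7 and 9 it was 8.11, 9.09 and 10.3. A probe on in sham alone had to pass the higher limit of sham 2, so the imbalance rests in part on these limits. Of the 316 probes, 66 had a bound over 1, with ASCRP4011796 the largest. Another split of the arrays, sham 1, I/R 6 and I/R 7 against the rest, gave 337 such probes, and it puts both arrays of slide 1 on the same side. The splits that part the slide 1 arrays, other than the real one, gave at most 56. With the scanner's flag for signal positive and significant over background the gap was smaller. There the real split gave 154, sham 1, I/R 6 and I/R 7 against the rest gave 206, and the splits that part the slide 1 arrays gave at most 86. The count was 1139 without sham 1, 545 without sham 3, 518 without I/R 6 and 765 without I/R 9. Leaving out an array relaxes the rule and can only keep or raise the count, so these rises are no test of it.

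The tested circRNA probes were slightly higher in I/R under the main scaling, with a median difference of 0.15 and 63.7% of probes higher. The per-array medians were -0.89 ± 0.07 in sham and -0.83 ± 0.02 in I/R (SD, n = 3; exact two-sided permutation p = 0.3). The median difference was 0.06 on slide 1 and 0.19 on slide 2, and 0.09 without sham 3. It was 0.52 with no scaling and 0.04 with quantile normalization. Its direction depended on the scaling: with the percentile taken over probes detected on all arrays the median was -0.04 and 46.6% were higher. The direction of single circRNA probes is therefore given relative to the array's own percentile.

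**Figure D2:**
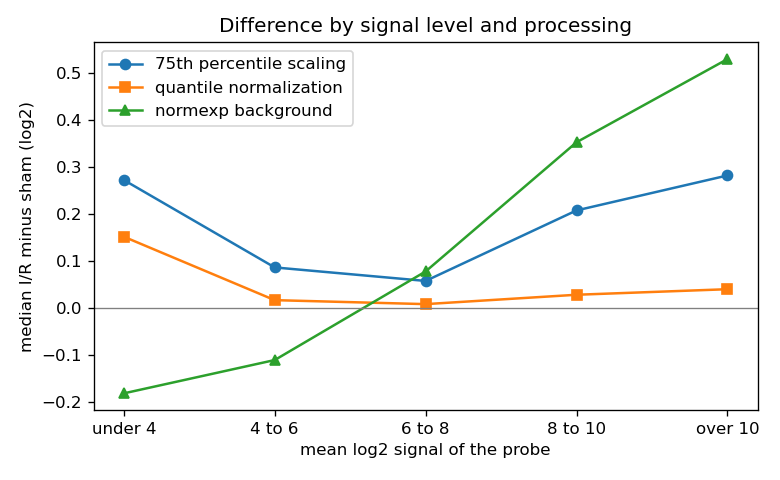
Median I/R minus sham difference (log2) of the tested circRNA probes in 5 classes of mean log2 signal, under 75th percentile scaling, quantile normalization and normexp background correction. With percentile scaling the medians run from 0.06 to 0.28, and with normexp from -0.18 in the dimmest class to 0.53 in the brightest.

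The circRNA signal was less concentrated in the brightest probes after I/R on every array. The 10 brightest circRNA probes of each array held 10.2%, 10.7% and 15.6% of the circRNA signal in sham 1, 2 and 3, and 7.01%, 7.19% and 9.07% in I/R 6, 7 and 9. The means were 12.1% ± 2.97 and 7.76% ± 1.14 (SD, n = 3), with every I/R array below every sham array and an exact two-sided permutation p of 0.1, the smallest possible. The difference of -4.37 percentage points was -2.66 without sham 3. The 100 brightest held 38.5% ± 4.38 in sham and 31.0% ± 2.54 in I/R, with an exact two-sided permutation p of 0.1. These shares do not depend on the scaling of an array, and a share of signal is not a share of molecules. On slide 1 the share of the 10 brightest was 10.2% in sham 1 and 7.01% in I/R 6.

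On their largest axis of variation the arrays did not group by operation. Pearson's r across tested circRNA probes, which are not independent replicates, averaged 0.936 within sham, 0.967 within I/R and 0.949 between the groups. Arrays of one slide averaged 0.961 and arrays of different slides 0.940. Sham 1 and I/R 6, the arrays of slide 1, had r = 0.970. On the first principal component (44.7% of the variance) they lay at -40.8 and -44.4, and sham 3 lay at 55.3. On the second component (23.1%) all I/R arrays, from 15.8 to 22.6, lay above all sham arrays, from -44.7 to 6.02.

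Spats1, Rab5a and Olfr1307 had the smallest p-values among named linear transcripts above background on at least 3 arrays, all with higher values in I/R on every array. None passed the threshold: limma over the 50 linear transcript probes called 0, with a smallest adjusted p of 0.0796, and 8 had an unadjusted p under 0.05. The RNA had been digested with RNase R, which degrades linear RNA. Values of linear transcripts here and below may therefore not follow their levels in the tissue. Spats1, a spermatogenesis-associated gene, was at -1.86 ± 0.13 in sham and -0.87 ± 0.31 in I/R (SD, n = 3), a difference of 0.99 (SE 0.29, adjusted p = 0.195), which was 0.23 with normexp. Rab5a, a GTPase of early endosomes, was not well above background on any sham array and was on all 3 I/R arrays, and its signal was too low to bound a fold (adjusted p = 0.231). Its sign turned with normexp, whose offset of 50 exceeds its mean signal (7.39 in sham and 15.6 in I/R). Olfr1307, an olfactory receptor gene, differed by 0.79 (SE 0.32, adjusted p = 0.231). With normexp 3 transcripts passed, Duox1, Prdx2 and Olfr1307. All are bright, with mean signals from 549 (Olfr1307 in sham) to 7600 (Duox1 in I/R). Bright circRNA probes as a set also had larger differences with normexp. Over a mean log2 signal of 10 their median was 0.53, against 0.28 under the main scaling. These passes are therefore not told apart from a general shift of bright probes. A transcript with no symbol in the reference used here, which had the smallest p, passed without sham 3, together with Acaa2, a mitochondrial enzyme of fatty acid oxidation, as well as with slide as a block and when only the 36 probes above background on at least 3 arrays were fitted, a fit made after the first had been seen (adjusted p with the block and in that fit of 0.0469 and 0.0416 in limma, the smallest adjusted p of any linear transcript ranged from 0.00988 to 0.572 over all alternatives). The transcript with no symbol was not well above background on any sham array, which makes it at least 1.73-fold higher in I/R. Its measured difference of 1.40 was 0.12 with normexp.

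Of these 36 linear transcripts, 29 were higher and 7 lower in I/R on average, with a median difference of 0.29. The counts were 24 and 12 with quantile normalization (median 0.18), 23 and 13 with the percentile over probes detected on all arrays (median 0.11), and 20 and 16 with normexp (median 0.02). Without sham 3 they were 23 and 13 (median 0.17). Antioxidant and oxidase transcripts chosen after their values were seen did not pass the threshold in the main fit. Prdx2, a peroxide-reducing peroxiredoxin, differed by 0.77 (SE 0.43), and Duox1, a dual oxidase that makes hydrogen peroxide, by 0.56 (SE 0.36). Their adjusted p was 0.476 and 0.526 in limma. Without single arrays the differences ran from 0.33 to 1.05 and from 0.28 to 0.81, lowest without sham 3. They were 0.52 and 0.27 with quantile normalization, and 0.97 and 0.80 with normexp, where both passed. Both are bright, and bright circRNA probes as a set also had larger differences with normexp. Anxa8, an annexin, differed by 0.70 (SE 0.38; 0.47 to 1.04 without single arrays). H2-Q7, a class Ib histocompatibility gene, was lower on all 3 I/R arrays, by -0.45 (SE 0.29; -0.54 to -0.27 without single arrays, -0.21 with normexp), and did not pass the threshold.

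Only 4 of the 36 transcripts belonged to the gene lists fixed before the data were examined, 1 in each of 4 lists, so no list could be tested. Gsdmd, the pore-forming protein of pyroptosis in the cell death list, was at 2.08 ± 0.45 in sham and 1.66 ± 0.42 in I/R (SD, n = 3), a difference of -0.42 (95% interval -1.22 to 0.37), which ran from -0.65 to -0.16 without single arrays and was -0.19 with normexp. Gpi1, a glycolytic isomerase in the hypoxia list, differed by 0.30 (interval -0.38 to 0.98; 0.19 to 0.50 without single arrays, 0.06 with normexp). Cpt1a, which carries fatty acids into mitochondria, differed by 0.28 (interval -0.39 to 0.95; 0.08 to 0.43 without single arrays), and its sign turned with normexp. Chgb, a granule protein of enteroendocrine cells, differed by -0.08 (interval -1.20 to 1.04; -0.48 to 0.36 without single arrays). Actb, the cytoskeletal actin often used as a reference, differed by -0.66 (interval -1.90 to 0.58; -1.13 to -0.20 without single arrays, -0.37 with normexp), with SDs of 0.86 and 0.91.

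**Figure D3:**
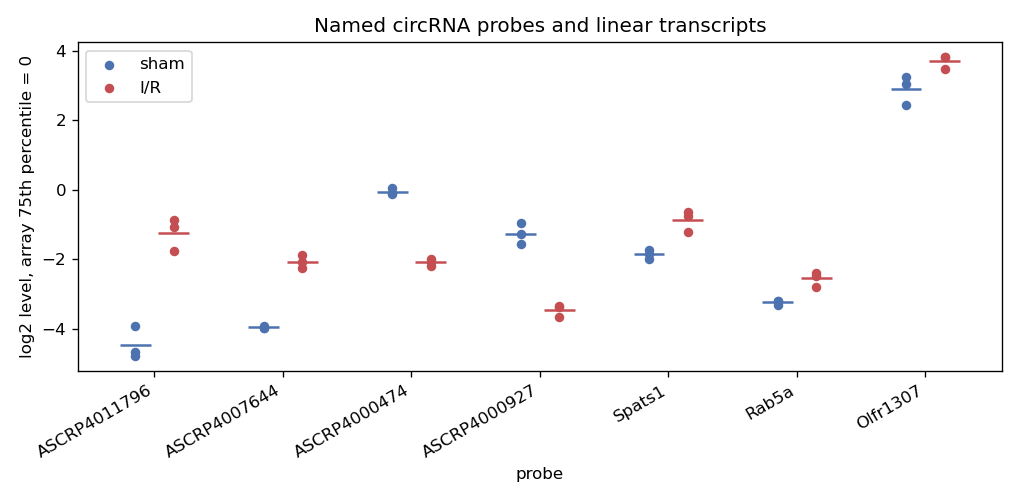
Level on each array (points) and group mean (lines) of 4 circRNA probes and 3 linear transcripts, as log2 relative to the array's 75th percentile, for sham (blue) and I/R (red), n = 3 each. ASCRP4011796, ASCRP4007644, Spats1, Rab5a and Olfr1307 lie higher in I/R and ASCRP4000474 and ASCRP4000927 lower. Sham values of ASCRP4011796, ASCRP4007644 and Rab5a and I/R values of ASCRP4000927 were not well above background, and none passed the adjusted threshold.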

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

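The tests of other probes, of shared thresholds and of other splits were chosen after the results were seen, while the count at an unadjusted p under 0.05 and slide as a block were planned. The comparisons in the Results did not use the 35 custom, control and negative probes well above background on all 6 arrays. Of these, 3 were higher on every I/R array than on every sham array and 5 were lower on every one, where chance gives 1.75 each way. The control spot eQC-39 was 1.46 higher in I/R on the log2 scale (2.04 ± 0.98 in sham and 3.49 ± 0.35 in I/R, SD, n = 3). The custom probe CUST_1 was 1.13 higher (3.16 ± 0.69 and 4.29 ± 0.30), and CUST_10 was 0.41 higher (-0.26 ± 0.16 and 0.15 ± 0.18). What these probes target is not given in the sources used here. Of the 5 lower probes 4 were circRNA controls, with differences of -0.79, -0.48, -0.39 and -0.27, and the fifth was a negative probe at -0.55. All 11 circRNA control probes and 11 of the 12 kinds of control spot, eQC-39 being the exception, were lower in I/R on average under the 75th percentile scaling. The kinds of control spot are not independent. DCP_22_0 and E1A_r60_a22, for example, ran alike over the arrays, at 0.90 and 0.95 on sham 1 and -0.13 and -0.19 on I/R 9. The 11 circRNA control probes were also all lower with quantile normalization, and 10 were with normexp, but without scaling 8 were higher and 3 lower.

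More circRNA probes were well above background on the I/R arrays. With one signal threshold for all arrays the lowest I/R array still held 280 more probes than the highest sham array, which argues against the noise floor of single arrays as the whole cause. With one threshold on the scaled level that gap was -98, but the scaling itself draws such counts together, so this decides nothing about overall brightness of the array. A higher yield of circRNA after I/R or more labelled material could each raise the count, and these stay open.

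More circRNA probes than 5% reached an unadjusted p under 0.05, an excess that lay in dim probes, under a mean log2 signal of 6. As many as the real 801 were found in 3 of the 10 splits of the arrays into 3 and 3, with 1431 the highest of the others, and 10 splits are too few for a share under 0.05. That split and another with 941 both put sham 1 and I/R 6, the arrays of slide 1, on the same side. With slide as a block the real count was 1179, and the highest of the other 5 splits that part the arrays of each slide evenly was 484, but 6 splits are also too few. The groups are balanced over the slides, so the block leaves the differences unchanged for the 9477 probes with a value on every array and is no test of a slide difference. For probes past the adjusted threshold all 10 splits gave 0, and for linear transcripts at an unadjusted p under 0.05 the real count was 8, reached in 2 of the 10 splits, with 10 the highest of the others; these splits are also too few.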

How the results depend on the processing

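The alternatives for linear transcripts, the share of the 10 brightest probes and the slides were chosen after seeing the data, as were the median difference over all tested probes with another percentile set, the on probes under other settings, and detected probes with shared thresholds or without single replicates. The groups share no replicate numbers, so only slide was blocked. Host gene lists and agreement within host genes were not run. Where no cause is named, it was not tested. The count of 0 differential circRNA probes was the same in 18 of 20 alternatives, including each replicate left out; it was 4 with array weights and 785 at an unadjusted p under 0.05 and a fold of 1.5.

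Probes at an unadjusted p under 0.05 (801) numbered 1284 with normexp, 1410 with no filter (more probes tested), 462 with probes above background on all 6 arrays (fewer tested), 1656 with array weights, and 359 to 1172 without single replicates. The percent of them higher in I/R (64.7%) was 40.9% with quantile normalization, 35.7% with normexp and quantile normalization, 30.3% with the percentile over probes detected on all arrays, 42.3% with no filter, 45.5% with probes above background on all 6 arrays, 36.7% in the authors' value table, and 49.9% to 77.8% without single replicates. The median difference over all tested probes reversed to -0.062 with normexp (40.9% of probes higher) and to -0.038 with the percentile over probes detected on all arrays (46.6% higher). The number of probes on in I/R alone (316) was 154 with the positive and significant flag and 325 to 1139 without single replicates. Leaving out a replicate can only keep or raise this count.

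The 4 named circRNA probes kept their direction in all alternatives and passed the threshold only with array weights, but shrank with normexp and in the authors' value table, where ASCRP4011796 was 0.56 and ASCRP4000474 -0.75. They were picked for their small p-values on these same arrays, so the kept direction is no test of them. Linear transcripts past the threshold (0) numbered 3 with normexp (all bright), 1 with slide as a block, 1 with only probes above background on at least 3 arrays, and 0 to 2 without single replicates (2 without sham 3). Those at an unadjusted p under 0.05 (8) numbered 3 with quantile normalization, 5 with only probes above background on at least 3 arrays, and 2 to 11 without single replicates (4, 3 and 2 without sham 2, I/R 6 and 7). Rab5a, undetected in sham, reversed to -0.11 with normexp. The correlation between slides (0.45) was 0.77 with normexp, where I/R 7 minus I/R 9 gave 0.53 and another labelling 0.38, and 0.61 over probes above background on all 6 arrays. Detected probes and the share of the 10 brightest probes kept their direction in every alternative run, but the scaled threshold, which draws counts together, gave a difference of 132 probes, not 2454. Signal over background limits the 3807 of 9492 tested probes below background on at least 1 array.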

Other observations

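All tests in this part were chosen after the results were seen. The I/R minus sham differences of circRNA probes were alike on the 2 slides, which share no array. Across 9477 probes, which are not independent replicates, I/R 6 minus sham 1 correlated with the mean difference on slide 2 at r = 0.45 (Spearman's rho 0.47), and 68.9% of probes had the same sign. The other 2 ways of dividing the slide 2 arrays into pairs gave r = 0.00 and -0.19. The sign of these is arbitrary, so only their size compares.

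Each of the 4 I/R and sham pairs on slide 2 gave a positive r, from 0.21 to 0.47, but I/R 7 minus I/R 9, a pair from the same group, gave 0.18. Removing each array's trend with the level left r at 0.46, which argues against overall brightness of the array acting through the level. Over probes above background on all 6 arrays r was 0.61, which argues against dim probes and the background floor. Over 65 probes that are not for circRNAs r was 0.66. On these last 2 sets of probes I/R 7 minus I/R 9 gave 0.33 and 0.43. The other ways of dividing the slide 2 arrays gave 0.06 and -0.33 on the first set and 0.10 and -0.36 on the second. In the authors' value table r was 0.50, and these other ways gave -0.08 and -0.41. The likeness may therefore come from a difference shared by all probes, such as RNA integrity, digestion or labelling, as well as from I/R itself. An effect of I/R that is particular to circRNAs stays an untested hypothesis.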
